A study of Mus musculus with 9 samples.

How the data were processed

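RNA from whole liver of 9 male FVB mice was sequenced, 3 libraries in each of 3 groups. Total RNA was extracted with Trizol and libraries followed standard Illumina protocols, per the labels' protocols, which name no kit and do not say whether it marks strand. The groups were taken from the labels. CTRL mice were 13, 13 and 17 weeks old. MODEL1 mice were each 18 weeks old and had received plasmids for NFE2L2 (the transcription factor NRF2) with the G31A change and CTNNB1 (beta-catenin) with the T41A change. MODEL2 mice were 19, 20 and 22 weeks old and had received NFE2L2 T80K with CTNNB1 T41A. Both pairs were given as 20 µg of each plasmid in 2 ml saline by hydrodynamic tail vein injection, which drives plasmid into hepatocytes, with a Sleeping Beauty transposase that inserts the cargo into the genome. The labels do not say whether the CTRL mice were injected. The series' design text describes a control group given wild-type NFE2L2 with T41A beta-catenin and examined weeks after injection. The sequenced CTRL mice, at 13, 13 and 17 weeks, had not reached the age this gives, so what they received remained unclear.

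The deposited table held raw counts, whole-number read counts per gene symbol with no normalization, for 24419 symbols. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0 and HTSeq 0.11.2 were used with mouse genome build mm10. The notes do not state the role of each tool, the annotation or the strand setting of the counting. Every column belonged to one library, and the table had no line for unassigned reads. Library totals ran from 219504 to 325177 counts, and 9512 symbols had 0 counts in all libraries. At these depths 3 counts in a library, the upper limit that a count of 0 allows, corresponded to 9.23 to 13.7 CPM, counts scaled by library size. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

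Symbols were placed on mm10 with GENCODE M21 gene models. Of the 24419 symbols, 23333 matched directly and 667 through a RefSeq synonym, while 44 matched several loci and 375 matched none. For each of the 24000 matched symbols, exon bases shared with an exon of another gene on the opposite strand were counted, and the result was checked against bedtools. The table does not state how reads were assigned to strands, so each gene measured below is given, in 1 of the places where it is named, with its opposite-strand exon neighbour where it has one, or with the nearest gene on that strand where this lies within about a kilobase. Reads of such pairs cannot be assigned to one gene with certainty. Overlap with an intron of a gene on the opposite strand is not given, so a gene named without a neighbour can still have such an overlap. Genes of near-identical families (Gsta, Gstm, Cyp2, Cyp3a, Saa, Fth1 and Ftl1 with their pseudogenes, olfactory, Mrgpr and H2-M10 genes) can also share reads.

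Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group factor and its default minimum count of 10, which left 2639 genes, and libraries were scaled by the trimmed mean of M values. The quasi-likelihood F test was fitted to all 9 libraries with 1 coefficient per group, and the 4 comparisons were contrasts of that fit. p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F, and all tests were two-sided. The common biological coefficient of variation was 0.259. Where a group held 0 counts, a fold is given as a lower bound against 3 counts over the group's libraries together. Where it held 1 to 3 counts, the ratio of scaled counts is given with its exact 95% counting interval. CPM values are given as mean ± SD.

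Before the data were examined, 30 gene lists, the comparisons, their tests, most alternative settings and the rule for named genes were fixed. The rule named Nfe2l2, Ctnnb1, Keap1 and Cul3 always. It also named, for each model against CTRL, the called members of each list with the largest changes, up to 4 for the first 7 lists and up to 2 for the others. For each comparison it named the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 2, non-overlapping libraries and a symbol other than a provisional one. For MODEL2 against MODEL1 it named up to 4 called members of every list. Counts of named genes below cover these genes alone; the other list members named were chosen after their values were seen, and counts over all called members are given beside them. The filter left 16 of 38 NRF2 targets, 10 of 16 pericentral, 5 of 18 periportal, 3 of 16 Wnt feedback and 4 of 25 cell cycle genes to test. A gene could pass the filter through the group where it was high, which favours changed members among those tested. Lists with at least 3 tested members, 12 of the 30, were tested with camera in limma 3.58.1 on voom weights with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Another 9 lists had 1 or 2 tested members, for which members are given singly. The remaining 9 had 0 tested members: male-biased liver genes, antigen presentation, markers of macrophages, T and NK cells, B cells, neutrophils and cholangiocytes, stellate cell and matrix genes, and the mitochondrially encoded mRNAs, of which 0 of 12 were symbols of the table.

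The fit was tested on simulated data for MODEL1 against CTRL, in 10 runs with 200 of the 2639 genes changed. It recovered 28.7% (19 to 40) of genes changed 2-fold and 81.7% (76 to 86) of those changed 4-fold, and 3.84% of calls were false on average, at most 6.35%. A 16-member list changed 2-fold was called in 10 of 10 runs with either correlation, and 2 of 110 tests of other lists were called. Simulated genes were drawn independently of each other, whereas the estimated correlation of the NRF2 targets in the data was 0.267. The runs therefore do not show which correlation setting is right for the data, nor the power of the estimated one there. Unchanged groups set against the same simulated CTRL libraries gave the overlap between the models from independent variation of genes alone.

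The settings varied were, as fixed beforehand, size factors by relative log expression, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, age in weeks as a covariate, an adjusted p threshold of 0.01, glmTreat against a log2 fold change of 1, DESeq2 1.42.0, fits of the compared groups alone, and each library left out in turn. Further settings were chosen after seeing the data: only genes with no opposite-strand exon, no Rn45s and Lars2, and no libraries with over 8% of counts in Rn45s. Where an arm keeps 1 library, that library is assumed to vary like the other groups. Annotation and figures were made in Python 3.11.15.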

Results

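Gene counts were measured in liver from 3 groups of 3 male FVB mice: CTRL, MODEL1 (NFE2L2 G31A with CTNNB1 T41A) and MODEL2 (NFE2L2 T80K with CTNNB1 T41A). Total counts were 297541, 247642 and 243876 in CTRL replicates 1 to 3, 304222, 219504 and 325177 in MODEL1, and 288547, 241205 and 248443 in MODEL2. Albumin (Alb), the main secreted hepatocyte protein, held 94 to 337 counts per library, and the 20 hepatocyte function genes together held 0.139% to 0.331% of the counts. Symbols with an exon on the opposite strand of another gene were 24.2% of the 24000 placed on the genome and held 79.0% of their counts. Per library they held 72.9% ± 5.12 of all counts in CTRL, 67.9% ± 3.76 in MODEL1 and 77.8% ± 0.960 in MODEL2 (SD, n = 3). Rn45s, the ribosomal RNA precursor, held 10.3%, 6.89% and 2.43% of counts in CTRL replicates 1 to 3, 13.4%, 2.68% and 8.62% in MODEL1, and 4.11%, 2.73% and 2.20% in MODEL2. The 3 libraries over 8%, CTRL replicate 1 and MODEL1 replicates 1 and 3, are called rich in Rn45s below. Within CTRL and within MODEL2 the older mice had the lower Rn45s shares, while the MODEL1 mice did not differ in age. The settings with age as a covariate and without the libraries rich in Rn45s are therefore not independent checks. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.855 to 0.899 between libraries of a group, 0.600 to 0.673 between CTRL and MODEL1, 0.711 to 0.775 between CTRL and MODEL2, and 0.796 to 0.851 between the models.

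**Figure D1:**
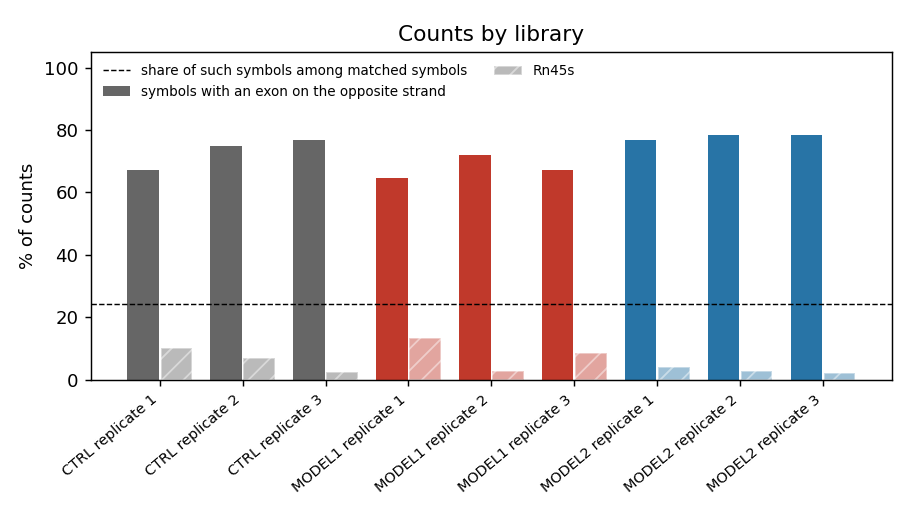
Share of each library's counts (%, y axis) held by symbols with an exon on the opposite strand (solid bars) and by Rn45s (hatched bars) in the 9 libraries (x axis, coloured by group). Solid bars run from 64.7% to 78.4%, against 24.2% of placed symbols (dashed line), and Rn45s from 2.20% to 13.4%.

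The injected genes and the partners of NRF2 were too low for edgeR's test, so ratios of their counts are given with intervals that cover counting error only. Nfe2l2 (mm10 chromosome 2, 75675513 to 75704641) held 15 counts over the 3 CTRL libraries, 25 in MODEL1 and 7 in MODEL2, or 21.5 ± 6.02, 33.1 ± 25.1 and 9.59 ± 2.93 CPM. The ratio was 1.41 (0.716 to 2.88) in MODEL1 and 0.438 (0.151 to 1.14) in MODEL2 against CTRL, and 0.310 (0.113 to 0.737) in MODEL2 against MODEL1, where the libraries of the groups overlapped and MODEL1 replicate 2 held 14 of the 25 MODEL1 counts. Its nearest opposite-strand gene, E030042O20Rik, lies 129 bp away. Ctnnb1 (chromosome 9, 120929216 to 120960507; exon of Ulk4 on the opposite strand) held 8, 23 and 16 counts, a ratio of 2.44 (1.05 to 6.30) in MODEL1 and of 1.88 (0.757 to 5.06) in MODEL2 against CTRL, and of 0.770 (0.3802 to 1.52) in MODEL2 against MODEL1, with overlapping libraries in each. Keap1, the adaptor that targets NRF2 for degradation, held 2, 9 and 9 counts and has an opposite exon of Gm16754, and Cul3, its ubiquitin ligase scaffold, held 3, 8 and 10. The intervals of Keap1 and Cul3 include 1 in each of these comparisons. Expression from the injected plasmids could not be told from that of the endogenous genes, and the labels' groups could not be checked on them.

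MODEL1 was compared with CTRL to describe liver carrying NFE2L2 G31A and CTNNB1 T41A. Genes of the NRF2 antioxidant and detoxification programme rose together. Of the 16 tested targets, from 38 listed, 15 were higher (15 adjusted over the list alone), and the median log2 fold change of the 16 was 3.48. All 3 MODEL1 libraries lay above all 3 CTRL libraries for each of the 15. Being called favours such separation, which all 40 called members of the lists showed, so it is not further support. The NRF2 list's camera adjusted p was 3.8e-10, but 0.178 with an estimated correlation (range over 20 alternatives 7.9e-29 to 0.178), and 0.00242 with fry. Abcc4, an efflux transporter (chromosome 14, 118482692 to 118706219), went from 1.40 ± 2.42 to 229 ± 82.4 CPM, on 1 and 181 counts, a ratio of 153 (27.2 to 6089; edgeR adjusted p = 1.4e-07). Gstm4, a glutathione transferase, had a ratio of 95.3 (26.1 to 792) on 2 and 225 counts. The ratio of Srxn1, sulfiredoxin, was 59.3 (10.3 to 2375), and that of Ugdh, UDP-glucose dehydrogenase, was 26.7 (7.09 to 225). Abcc2 had a log2 fold change of 0.90 ± 0.48 (SE) and an adjusted p of 0.198. Of the tested targets, 1 has an opposite-strand exon, Ftl1 (Gm10252). Of the 3 tested pentose phosphate and NADPH enzymes, transketolase (Tkt) rose by 3.40 ± 0.68 log2 units (adjusted p = 0.000685) and Rpe did not pass (adjusted p = 0.548; opposite exon of Kansl1l). The list did not pass (camera adjusted p = 0.661).

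**Figure D2:**
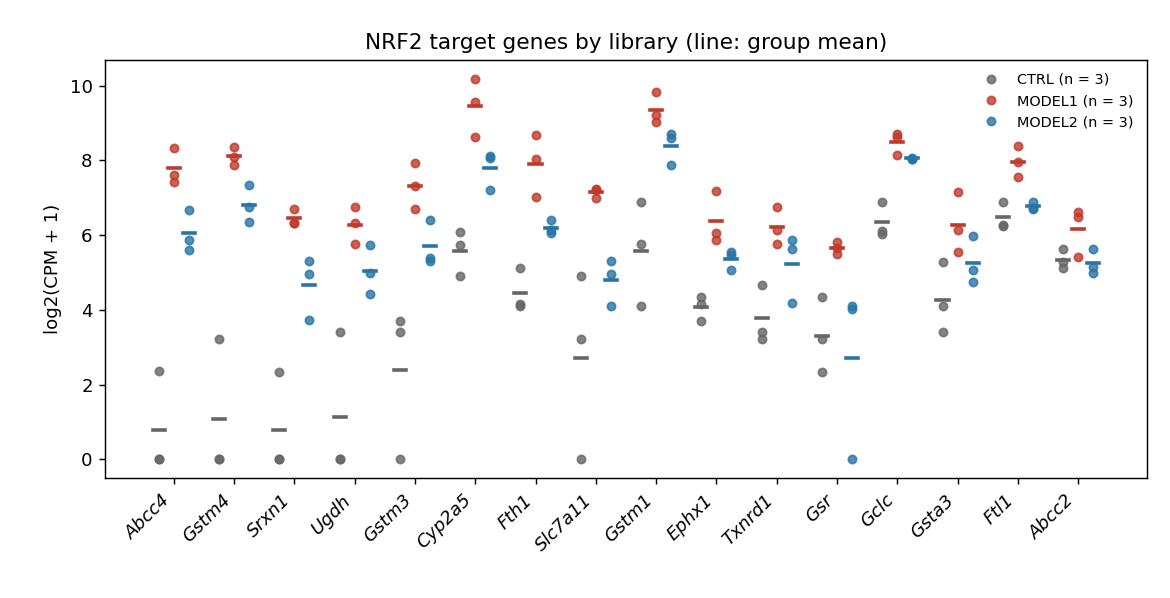
Level of the 16 tested NRF2 targets (x axis) as log2(CPM + 1) (y axis) in each library (points) with group means (lines), for CTRL, MODEL1 and MODEL2 (n = 3 each). For 15 of the 16 genes all MODEL1 points lie above all CTRL points, and 9 were called higher in MODEL2 than in CTRL.

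Some of the genes that hepatocytes express around the central vein rose in MODEL1, and some of those expressed around the portal tract fell. Of 10 tested pericentral genes 5 were higher (6 adjusted over the list alone; median log2 fold change 1.84; camera adjusted p = 0.0138). This adjusted p was 0.398 with an estimated correlation (range over 20 alternatives 3.3e-06 to 0.398). Glul, glutamine synthetase, rose by 3.77 ± 0.56 log2 units (edgeR adjusted p = 2.7e-05; opposite exon of Teddm2). The glutamate transporter Slc1a2 rose by 3.40 ± 0.83 (opposite exon of Gm13872), Cyp1a2 by 3.04 ± 0.46 and Gulo by 3.02 ± 0.79, while Cyp2e1 had a log2 fold change of 0.04 ± 0.33. Of 5 tested periportal genes 3 were lower (3 adjusted over the list alone; median log2 fold change -2.45; camera adjusted p = 0.0138). With an estimated correlation it was 0.178 (range over 20 alternatives 2.6e-06 to 0.178). Pck1, the gluconeogenic enzyme, fell by 4.18 ± 0.68 log2 units, from 163 ± 57.1 to 8.44 ± 7.31 CPM. Cps1, the first enzyme of the urea cycle, fell by 2.88 ± 0.57 and the IgA transporter Pigr fell by 2.45 ± 0.54. Of 3 tested Wnt feedback targets, Notum, a secreted Wnt inhibitor, went from 1 to 167 counts, a ratio of 141 (25.05 to 5621), and has opposite exons of Notumos and Myadml2os. Tcf7 and Ccnd1 (opposite exon of LTO1) had log2 fold changes of 0.11 ± 0.64 and -0.14 ± 0.33, and the list's camera adjusted p was 0.331.

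**Figure D3:**
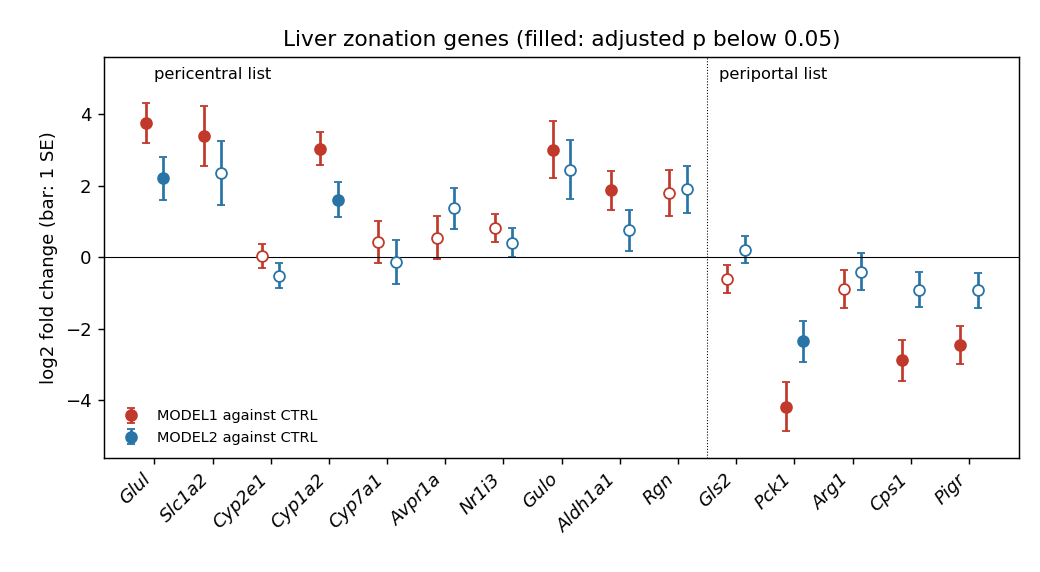
Log2 fold change against CTRL (y axis; bars, 1 SE) of the tested pericentral and periportal genes (x axis) in MODEL1 and MODEL2 (n = 3 libraries per group). Filled points have an adjusted p under 0.05: 5 of 10 pericentral and 3 of 5 periportal genes in MODEL1, and 2 and 1 in MODEL2.

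Secretory and metabolic hepatocyte genes mostly fell in MODEL1 where they changed. Of 13 tested hepatocyte function genes 4 were lower and 1 higher (5 lower and 1 higher adjusted over the list alone; median log2 fold change -0.84; camera adjusted p = 0.067). The list passed with no filter (0.0121), with the 1 CPM filter (0.0170), without CTRL replicate 2 (0.0372), without MODEL1 replicate 2 (0.0267) and with fry (0.0369), while its adjusted p was 0.464 with an estimated correlation (range over 20 alternatives 0.0121 to 0.742). Apoa1 had a log2 fold change of -1.27 ± 0.22, Fga, a fibrinogen chain, of -1.15 ± 0.33, Alb of -0.99 ± 0.24 and Cyp3a11 of -1.99 ± 0.59, while the uptake transporter Slco1b2 rose by 1.68 ± 0.54. Of 5 bile acid genes, Slc27a5, the bile acid coenzyme A ligase, fell by 3.75 ± 0.36 log2 units (edgeR adjusted p = 4.6e-08; Trim28 lies 922 bp away on the opposite strand), and the list's camera adjusted p was 0.331. Of 4 acute phase genes, Saa4 fell by 1.22 ± 0.31, Fgb fell by 1.43 ± 0.37 and Itih4 fell by 1.56 ± 0.46 (3 adjusted over the list alone; median log2 fold change -1.33; camera adjusted p = 0.0379). The list's adjusted p was 0.398 with an estimated correlation (range over 20 alternatives 0.00847 to 0.398). It was 0.0973 without CTRL replicate 3, 0.0841 without MODEL1 replicate 1, 0.0579 without MODEL1 replicate 3, 0.261 without the 3 libraries rich in Rn45s, and 0.296 and 0.257 with no filter and with the 1 CPM filter. Both tested female-biased genes rose: Cyp2b9 went from 0 to 64 counts, at least 18.1-fold, and Cyp2a4 from 1 to 145, a ratio of 123 (21.7 to 4885; opposite exon of Gm42375).

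Of 4 tested cell cycle genes Ccna2, cyclin A2, rose by 0.88 ± 0.27 log2 units in MODEL1 (opposite exon of Exosc9) and Tk1, thymidine kinase, fell by 2.09 ± 0.22 (opposite exon of Afmid), with a camera adjusted p of 0.811 for the list, whose median was 0.33 and mean -0.14. Clec9a, the tested dendritic cell marker, rose by 1.62 ± 0.31 log2 units (edgeR adjusted p = 0.000452); Clec1a lies 9 bp away on the opposite strand. Eng, the tested endothelial marker, had a log2 fold change of -0.95 ± 0.28 (opposite exon of Fpgs). No tested member was called in MODEL1 or in MODEL2 against CTRL among oncofetal genes (3 tested), cholesterol synthesis (5), fatty acid oxidation (4), fatty acid synthesis, glycolysis and interferon response (2 each), or ATF4 targets, erythroid and exocrine pancreas markers (1 each). Of these 21 genes edgeR and DESeq2 each called 0 in either model, and at an unadjusted p under 0.05 edgeR gave 2 in MODEL1 (Fdft1, with an opposite exon of Ctsb, and Irf7, with one of Phrf1) and 1 in MODEL2 (Fdft1). The oncofetal, cholesterol and fatty acid oxidation lists had camera adjusted p of 0.811, 0.842 and 0.331 in MODEL1 and 0.643, 0.833 and 0.504 in MODEL2. The alpha-fetoprotein gene Afp had log2 fold changes of -0.10 ± 0.33 in MODEL1 and 0.38 ± 0.32 in MODEL2.

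Outside the lists, the largest rises in MODEL1 were in genes with 0 to 2 counts in CTRL. Kcna4, a potassium channel (chromosome 2, 107290639 to 107298502), went from 0 to 352 counts, at least 99.4-fold higher. Alpk3 was at least 79.1-fold and Ttc27 at least 46.3-fold higher. The ratio was 500 (89.4 to 19775) for Mrgpra3, on 1 and 590 counts, and 416 (115 to 3439) for Lrrc75b, on 2 and 982 counts. The largest falls were in Olfr541, on 165 and 3 counts (ratio 0.0154, 0.00314 to 0.0458), Txnip, the thioredoxin-interacting protein (-5.43 ± 0.92; 980 ± 1359 CPM in CTRL; opposite exon of Gm15441), D7Ertd143e (-5.09 ± 0.51; not placed on the genome), Gpr171, on 64 and 2 counts (ratio 0.0265, 0.00314 to 0.0996), and Mfhas1, on 63 and 3 (ratio 0.0403, 0.00810 to 0.123; opposite exon of Gm16793).

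In total 602 of 2639 genes differed between MODEL1 and CTRL by edgeR's test, 313 higher and 289 lower. Of these 269 rose and 230 fell by at least 2-fold in the fit, and 338 (56.1%) have an opposite-strand exon. Called genes had one slightly less often than the other tested genes (odds ratio 0.80, Fisher p = 0.0178, over genes, which are not independent). The number was 299 with age as a covariate, 261 among the 1047 tested genes with no opposite-strand exon, and 274 without the 3 libraries rich in Rn45s. Age as a covariate ended the call of 10 of 34 named genes and left 11 NRF2 targets higher. With age Cyp3a11 was at -0.61 ± 0.81 (adjusted p = 0.739), Slco1b2 at 0.60 ± 0.69 (0.686), Txnip at -2.62 ± 1.34 (0.256), Gulo at 2.03 ± 1.16 (0.327) and Pigr at -1.72 ± 0.74 (0.163). Slc1a2 was at 3.0 ± 1.30 (0.165), Ccna2 at 0.80 ± 0.43 (0.280), Eng at -1.04 ± 0.43 (0.140), Fgb at -1.50 ± 0.52 (0.0692) and Itih4 at -1.96 ± 0.64 (0.0542). Of all 40 called list members, age ended 15 calls, leaving out the libraries rich in Rn45s 14, and leaving out 1 library 10. Alb (0.194) and Saa4 (0.129) lost theirs with age, Alb (0.475), Apoa1 (0.0612), Fga (0.191) and Saa4 (0.173) without the libraries rich in Rn45s, and Fga without CTRL replicate 3 (0.0740) or MODEL1 1 (0.0632). The median of the NRF2 targets was 3.48 with age, while their median SE went from 0.60 to 0.93. In DESeq2 Pigr (0.107) and Slco1b2 (0.0699) did not pass, nor did Ccna2 with no filter (0.0846). Leaving out the libraries rich in Rn45s ended 10 calls, those of Cps1 (0.0962), Pigr (0.0631), Gulo (0.165), Clec9a (0.0640), Mfhas1 (0.0574), Cyp3a11 (0.102), Slco1b2 (0.282), Itih4 (0.376), Fgb (0.256) and Eng (0.179). Among 34 genes named in MODEL1, 6 lost their call when 1 library was left out. These were Slco1b2 (adjusted p 0.120 without CTRL replicate 1, 0.0955 without CTRL 2, 0.0705 without MODEL1 2 and 0.0693 without MODEL1 3), Ccna2 (0.0557 without CTRL 2, 0.0980 without MODEL1 2, 0.0510 without MODEL1 3), Cyp3a11 (0.0618 without CTRL 2, 0.0853 without MODEL1 2), Eng (0.0571 without CTRL 2, 0.0608 without MODEL1 1, 0.0501 without MODEL1 2), Itih4 (0.0748 without CTRL 3, 0.0612 without MODEL1 1, 0.0578 without MODEL1 3) and Fgb (0.0535 without MODEL1 3).

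MODEL2 was compared with CTRL to describe liver carrying NFE2L2 T80K and CTNNB1 T41A. No group is labelled with an NFE2L2 or a CTNNB1 change alone. In either model their effects against CTRL therefore cannot be told apart, nor from those of age or injection. NRF2 targets rose here too: 9 of 16 tested targets were higher (9 adjusted over the list alone; median log2 fold change 1.69), each with all 3 MODEL2 libraries above all 3 CTRL libraries, a separation that being called already favours. The list's camera adjusted p was 6.2e-05, but 0.501 with an estimated correlation (range over 20 alternatives 5.3e-14 to 0.501) and 0.0564 with fry. Abcc4 had a ratio of 47.8 (8.21 to 1926) on 1 and 51 counts, with 68.9 ± 28.8 CPM in MODEL2. The ratio was 39.9 (10.7 to 334) for Gstm4, 18.8 (2.9998 to 777) for Srxn1 and 11.7 (2.92 to 102) for Ugdh. Gclc, the catalytic subunit that makes glutathione's precursor, rose by 1.66 ± 0.31 log2 units (edgeR adjusted p = 0.000632), and Slc7a11 had a log2 fold change of 1.24 ± 0.72 (adjusted p = 0.301). Tkt rose by 3.40 ± 0.69 log2 units (1 of 3 tested pentose phosphate and NADPH enzymes; camera adjusted p = 0.562).

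Of the 10 pericentral genes 2 rose in MODEL2, Glul by 2.21 ± 0.60 log2 units and Cyp1a2 by 1.62 ± 0.49 (6 adjusted over the list alone; median log2 fold change 1.49; camera adjusted p = 0.123). Of the 5 periportal genes Pck1 fell by 2.35 ± 0.57 (1 adjusted over the list alone; median log2 fold change -0.91; camera adjusted p = 0.140). Both lists passed with no filter (adjusted p 0.000498 and 0.0105) and with the 1 CPM filter (0.00131 and 0.0230), while with an estimated correlation their adjusted p was 0.501 each (ranges over 20 alternatives 0.000498 to 0.501 and 0.0105 to 0.501). Notum went from 1 to 83 counts, a ratio of 77.8 (13.6 to 3111), while its list had a median log2 fold change of -0.13, a mean of 1.59 and a camera adjusted p of 0.578. Slc27a5 fell by 2.17 ± 0.31, Apoa1 had a log2 fold change of -1.28 ± 0.22 and Alb of -0.85 ± 0.24, the called 2 of 13 hepatocyte function genes (2 adjusted over the list alone; camera adjusted p = 0.123). This list passed with no filter (0.00808) and with the 1 CPM filter (0.0209; range over 20 alternatives 0.00808 to 0.501). Among cell cycle genes Ccna2 and Aurka, a mitotic kinase with Cstf1 146 bp away on the opposite strand, rose by 1.11 ± 0.27 and 1.05 ± 0.32, and Tk1 had a log2 fold change of -0.85 ± 0.21 (camera adjusted p = 0.643). The acute phase gene Itih4 had a log2 fold change of -1.37 ± 0.45 (2 members adjusted over the list alone; camera adjusted p = 0.157). Cyp2b9 went from 0 to 15 counts, at least 4.69-fold higher, and Cyp2a4 from 1 to 40, a ratio of 37.5 (6.36 to 1518).

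The largest rises in MODEL2 were at least 40.01-fold for Alpk3, 39.4-fold for Kcna4, 33.8-fold for Nfkbib (opposite exons of Ccer2 and Sirt2) and 20.9-fold for Thy1, each from 0 counts in CTRL, and a ratio of 336 (59.9 to 13297) for Mrgpra3. The largest falls were in Txnip (-5.86 ± 0.97), Olfr541 (ratio 0.0170, 0.00348 to 0.0507, on 165 and 3 counts), Btf3l4 (-3.71 ± 0.76; Txndc12 987 bp away), D7Ertd143e (-3.64 ± 0.45) and Rhobtb1 (-3.40 ± 0.78; opposite exon of A930033H14Rik).

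By edgeR's test 350 of 2639 genes differed between MODEL2 and CTRL, 219 higher and 131 lower, of which 206 (58.9%) have an opposite-strand exon (odds ratio against the other tested genes 0.93, Fisher p = 0.558). With age as a covariate the number was 71, 137 among genes with no opposite-strand exon, 207 without the 3 libraries rich in Rn45s, 223 without CTRL replicate 1 and 221 without MODEL2 replicate 2. Age as a covariate ended the call of 18 of 28 named genes and left 1 NRF2 target called. The median log2 fold change of the NRF2 targets was 2.32 with age, against 1.69 without (camera adjusted p = 0.000444, and 0.636 with an estimated correlation), and their median SE went from 0.65 to 1.33. Over all tested genes the median SE went from 0.42 to 0.88. Of the 18 genes, 11 had a smaller and 7 a larger change with age. Among them Abcc4 was at 3.13 ± 1.41 with age (adjusted p = 0.368), Tkt at 3.62 ± 1.45 (0.275), Pck1 at -2.69 ± 1.09 (0.278) and Slc27a5 at -1.71 ± 0.65 (0.227), while Glul was at 1.01 ± 1.14 (0.785), Tk1 at -0.76 ± 0.44 (0.511) and Txnip at -1.59 ± 1.84 (0.795). The others were Srxn1 (0.0796), Ugdh (0.253), Cyp1a2 (0.702), Ccna2 (0.538), Aurka (0.777), Apoa1 (0.425), Alb (0.765), Cyp2b9 (0.128), Itih4 (0.344), Btf3l4 (0.135) and Rhobtb1 (0.471). Leaving out the libraries rich in Rn45s ended 7 calls, those of Glul (0.112), Ugdh (0.124), Cyp1a2 (0.118), Aurka (0.183), Alb (0.0700), Cyp2b9 (0.0849) and Itih4 (0.102). Tk1 lost its call with no filter (0.0807) and with the 1 CPM filter (0.0530), as did Aurka (0.0950 and 0.0506) and Itih4 (0.252 and 0.174). The replicate block ended the calls of Cyp1a2 (0.0569), Aurka (0.0549) and Itih4 (0.0807), DESeq2 those of Aurka (0.0583) and Itih4 (0.129), the fit of the compared groups alone those of Cyp1a2 (0.0655) and Cyp2b9 (0.0552), and the fit of genes with no opposite-strand exon those of Alb (0.0885) and Itih4 (0.0876). Of all 23 called list members, age ended 20 calls (Gclc at 0.91, adjusted p = 0.586), leaving out the libraries rich in Rn45s 8, and leaving out 1 library 12. Of 28 named genes 10 lost their call when 1 library was left out. Without CTRL replicate 1 these were Aurka (adjusted p = 0.168), Alb (0.118), Cyp1a2 (0.109), Itih4 (0.103), Ugdh (0.0866), Glul (0.0863) and Cyp2b9 (0.0610). Without CTRL replicate 3 they were Itih4 (0.175), Ugdh (0.0694) and Cyp2b9 (0.0504), and without CTRL replicate 2 Cyp1a2 (0.101). Without MODEL2 replicate 1 they were Cyp1a2 (0.141), Itih4 (0.117), Aurka (0.0716), Glul (0.0692) and Srxn1 (0.0509). Without MODEL2 replicate 2 they were Itih4 (0.116), Aurka (0.101), Ugdh (0.0847), Cyp2b9 (0.0806), Ccna2 (0.0785), Alb (0.0776), Cyp1a2 (0.0686) and Glul (0.0524). Without MODEL2 replicate 3 they were Itih4 (0.103), Alb (0.0946), Aurka (0.0682) and Pck1 (0.0516), and Itih4 also lost its call without MODEL1 replicate 3 (0.0608).

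MODEL2 was set directly against MODEL1 to compare the NFE2L2 changes. NRF2 targets were lower in MODEL2: 7 of 16 were called lower (10 adjusted over the list alone; median log2 fold change -1.24), each with all 3 MODEL2 libraries below all 3 MODEL1 libraries, a separation that being called already favours. The list's camera adjusted p was 5.9e-10, but 0.237 with an estimated correlation (range over 20 alternatives 1.3e-13 to 0.237), and 0.0226 with fry. The cystine transporter Slc7a11 fell by 2.31 ± 0.53 log2 units, from 142 ± 12.8 to 28.3 ± 11.2 CPM (edgeR adjusted p = 0.0104). The ferritin heavy chain gene Fth1 fell by 1.85 ± 0.39 (Best1 lies 76 bp away on the opposite strand), Cyp2a5 fell by 1.74 ± 0.34 and Abcc4 fell by 1.71 ± 0.40. Rn45s held less of the MODEL2 libraries (3.01% ± 0.985) than of the MODEL1 libraries (8.25% ± 5.39), and the mice differed in age.

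Among zonation genes Glul fell by 1.56 ± 0.45 log2 units in MODEL2 against MODEL1 and Cyp1a2 fell by 1.42 ± 0.39, the called 2 of 10 pericentral genes (2 adjusted over the list alone; camera adjusted p = 0.0957). Cps1 rose by 1.97 ± 0.60, the called 1 of 5 periportal genes (2 adjusted over the list alone; median log2 fold change 1.53; camera adjusted p = 0.0413). The periportal call ended with an estimated correlation (adjusted p = 0.243; range over 20 alternatives 0.00339 to 0.243), with fry (0.0575), with the replicate number as a block (0.0565), without CTRL replicate 2 (0.0575), CTRL 3 (0.0548), MODEL1 1 (0.0956), MODEL2 2 (0.103) or the 3 libraries rich in Rn45s (0.172), and in the fit of the compared groups alone (0.0558). Pericentral genes passed without MODEL1 replicate 1 (0.00668) and without the libraries rich in Rn45s (0.00190), while their adjusted p was 0.648 with an estimated correlation (range over 20 alternatives 0.00190 to 0.648). Slc27a5 rose by 1.59 ± 0.39 and Tk1 by 1.24 ± 0.22 (the cell cycle list passed with fry alone, 0.0324), while Cyp2a4 fell by 1.71 ± 0.45 and Clec9a fell by 1.79 ± 0.31. The largest rises were in Pitx3 (ratio 39.9, 13.3 to 196, on 3 and 108 counts; opposite exon of Elovl3), H2-M10.6 (ratio 18.8, 6.09 to 94.3, on 3 and 51 counts), Onecut1, a hepatocyte transcription factor (3.60 ± 0.79), Nlrp5-ps (3.46 ± 0.30) and Spryd4 (3.40 ± 0.74; opposite exon of Gls2). The largest falls were in R3hdml (-3.49 ± 0.71), Gpr21 (-2.87 ± 0.75), Asb13 (-2.77 ± 0.34), Pmch (-2.67 ± 0.72; opposite exon of Parpbp) and Rnase4 (-2.61 ± 0.76).

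By edgeR's test 192 of 2639 genes differed between the models, 102 higher and 90 lower in MODEL2, of which 107 (55.7%) have an opposite-strand exon (odds ratio against the other tested genes 0.82, Fisher p = 0.193). The number was 125 with the replicate number as a block, 101 with age as a covariate, 72 among genes with no opposite-strand exon, 70 without the 3 libraries rich in Rn45s, 88 and 107 without MODEL1 replicates 2 and 3, and 79, 119 and 101 without MODEL2 replicates 1, 2 and 3. Age as a covariate ended 8 of 21 named calls and left 2 NRF2 targets lower. With age Slc7a11 was at -1.72 ± 0.80 (adjusted p = 0.266), Fth1 at -1.57 ± 0.57 (0.138), Cyp2a4 at -0.47 ± 0.81 (0.848), Pmch at -1.48 ± 1.38 (0.651) and Cps1 at 1.82 ± 0.70 (0.159), each smaller than without age. Glul was at -2.06 ± 0.61 (0.0630), Cyp1a2 at -1.63 ± 0.53 (0.0904) and Gpr21 at -4.09 ± 1.48 (0.139), each larger. The median of the NRF2 targets was -1.18 with age, and their median SE went from 0.47 to 0.67. The replicate block ended the calls of Glul (0.0882), Cps1 (0.0874), Cyp1a2 (0.0762), Rnase4 (0.0637), Gpr21 (0.0581) and Pmch (0.0559). Leaving out the libraries rich in Rn45s ended 11, those of Onecut1 (0.213), Cps1 (0.463), Slc7a11 (0.129), H2-M10.6 (0.0686), Spryd4 (0.184), Gpr21 (0.2025), Pmch (0.111), Rnase4 (0.147), Glul (0.0696), Slc27a5 (0.174) and Cyp2a4 (0.0813). Cps1 also lost its call with relative log expression (0.0564), in the fit of the compared groups alone (0.0544) and without Rn45s and Lars2 (0.0523), Gpr21 with no filter (0.0717) and with the 1 CPM filter (0.0587), and Rnase4 in DESeq2 (0.0577). Of all 14 called list members, age ended 9 calls, the replicate block 5, leaving out the libraries rich in Rn45s 7, and leaving out 1 library 11. Of 21 named genes 13 lost their call when 1 library was left out. Without MODEL1 replicate 2 these were Glul (adjusted p = 0.198), Cyp1a2 (0.192), Rnase4 (0.143), Cyp2a4 (0.129), Pmch (0.125), Abcc4 (0.0999), Gpr21 (0.0653), Fth1 (0.0622) and Slc27a5 (0.0578). Without MODEL1 replicate 3 they were Cps1 (0.125), Cyp2a4 (0.0915), Slc27a5 (0.0852), Gpr21 (0.0840), Pmch and Rnase4 (0.0797 each), Cyp1a2 (0.0761) and Glul (0.0536). Without MODEL1 replicate 1 they were Cps1 (0.121), Glul and Rnase4 (0.0670 each) and Gpr21 (0.0510). Without MODEL2 replicate 1 they were Rnase4 (0.168), Cps1 (0.133), Gpr21 (0.115), Glul (0.0756), Abcc4 (0.0659), Onecut1 (0.0656), Spryd4 (0.0612) and Cyp1a2 (0.0530). Without MODEL2 replicate 2 they were Cps1 (0.131), Glul (0.114), Rnase4 (0.102), Cyp1a2 (0.101), Pmch (0.0853), Gpr21 (0.0757), Abcc4 (0.0579) and Slc27a5 (0.0552). Without MODEL2 replicate 3 they were Glul (0.174), Cyp1a2 (0.141), Cyp2a4 (0.115), Pmch (0.104), Cps1 (0.0860), Slc7a11 (0.0674) and Slc27a5 (0.0569). Cps1 also lost its call without CTRL replicates 1 (0.0556) and 3 (0.0542).

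The models changed many genes in the same direction. Against CTRL, 264 genes were called in both with the same sign, 164 higher and 100 lower. The exception, Pitx3, was lower in MODEL1 (-2.56 ± 0.84) and higher in MODEL2 (2.58 ± 0.54). Of the 602 genes called in MODEL1, 570 had the same sign in MODEL2, a number that the shared controls raise. Of the 581 genes called on the mean of both models against CTRL, a choice that favours neither model and was made after seeing the data, 417 (71.8%) changed less in MODEL2 than in MODEL1. With no difference between the models about as many genes would change less in either one. Genes picked by the call of 1 model are picked for a large change in it, and with that bias the number was 524 (87.0%) of the 602 called in MODEL1 and 187 (53.4%) of the 350 called in MODEL2. Independent lists of these sizes would share 26.0 higher and 14.3 lower genes, and simulated unchanged groups against shared simulated controls shared at most 0 calls in 20 runs. The simulation held no differences between libraries that act on many genes at once, so it leaves out overlap from such differences among the real controls. Across genes the log2 fold changes correlated at r = 0.84 with a covariance of 1.31, against r = 0.515 (0.475 to 0.540) and a covariance of 0.104 (0.0951 to 0.115) in the simulation. With 3 CTRL libraries the controls cannot be split with at least 2 on each side, so part of the excess may come from the shared controls.

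**Figure D4:**
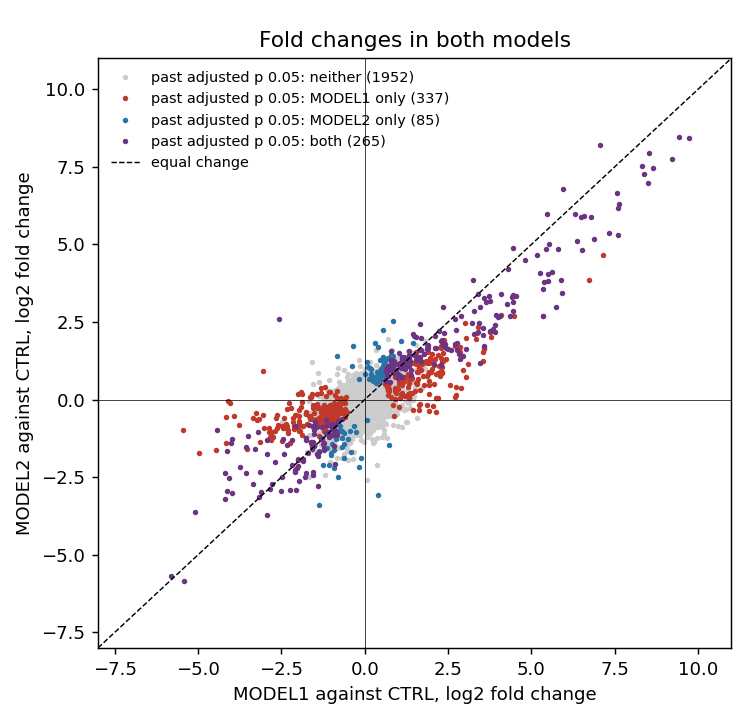
Log2 fold change of the 2639 tested genes in MODEL1 (x axis) and MODEL2 (y axis) against CTRL, coloured by whether the adjusted p was under 0.05 in both models (265), in MODEL1 alone (337), in MODEL2 alone (85) or in neither (1952). The dashed line marks equal change, and the genes called in both models lie on the same side of 0 on both axes except Pitx3.

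Taking the mean of both models against CTRL, edgeR called 581 of 2639 genes, 300 higher and 281 lower. Across both models 13 of 16 NRF2 targets were higher (14 adjusted over the list alone; median log2 fold change 2.52; camera adjusted p = 1.3e-07), 5 of 10 pericentral genes were higher (6 adjusted over the list alone; camera adjusted p = 0.0281) and 3 of 5 periportal genes were lower (3 adjusted over the list alone; 0.0246). With an estimated correlation these adjusted p were 0.2004, 0.411 and 0.2004. Kcna4 was at least 70.9-fold, Alpk3 at least 60.5-fold, Ttc27 at least 33.8-fold and Thy1, a cell surface glycoprotein, at least 28.8-fold higher, and Mrgpra3 had a ratio of 422 (75.5 to 16683). The largest falls were in Olfr541 (-5.74 ± 0.48), Txnip (-5.65 ± 0.72), D7Ertd143e (-4.36 ± 0.37), Crip3 (-3.69 ± 0.69; Slc22a7 407 bp away on the opposite strand) and Ackr2, a chemokine-scavenging receptor (-3.54 ± 0.44). The number of genes was 151 with age as a covariate, 236 among genes with no opposite-strand exon and 296 without the libraries rich in Rn45s, and age ended the calls of Txnip (-2.10 ± 1.46 with age; adjusted p = 0.512), Crip3 (-3.09 ± 1.27; 0.202) and Ackr2 (-2.06 ± 1.01; 0.3001).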

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

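The tests of dilution over all genes, of ribosomal RNA and of age were chosen after the result was seen. The results in this part were picked out because the effects of the models, each against the same CTRL libraries, differed in the direct test between them. NRF2 targets were lower in MODEL2 than in MODEL1, with a median log2 fold change of -1.24 (camera adjusted p = 5.9e-10 with the preset correlation between genes, but 0.237 with an estimated one), and the called members were headed by Slc7a11 (-2.31), Fth1 (-1.85), Cyp2a5 (-1.74) and Abcc4 (-1.71). If more control-like tissue in MODEL2 were the whole difference, its levels would lie between those of CTRL and MODEL1. Of the 192 genes called between the models, 17 (8.85%, against a bound of 5% set for this test) changed in the same direction against CTRL too. Both comparisons used the same MODEL2 libraries. Their mean share of counts in symbols with an opposite-strand exon was 77.8%, against 72.9% in CTRL and 67.9% in MODEL1. A shift of these libraries could also place genes outside that range, so the 17 genes do not decide on control-like tissue. For the NRF2 targets themselves control-like tissue stays open too. The 289 genes called lower in MODEL1 kept a median of 63.5% of their fall in MODEL2, which was not tested against the rises. The 15 called targets kept a median of 29.7% of their MODEL1 rise, against 45.4% for 298 other rises. This was a difference of -15.7 points (bootstrap interval -26.0 to -2.99) with a permutation p of 0.197. The reading was changed from in favour of dilution to undecided after seeing this interval. Interval and permutation both resample genes, which share the same libraries and are not independent replicates. Neither measures the spread between mice. At the preset correlation, ribosomal RNA share as a linear trend within groups is argued against, since with the log2 Rn45s share as a covariate the median was -1.53 (camera adjusted p = 3.6e-12, and 0.0652 with an estimated correlation), while the median of -1.80 without the libraries rich in Rn45s leaves 1 MODEL1 library and was set aside for that reason although it had met its bound. With age as a covariate the median was -1.18 (camera adjusted p = 5.4e-05 at the preset correlation, and 0.564 with an estimated correlation). All MODEL1 mice were 18 weeks old, so the fitted age trend rests on CTRL and MODEL2 mice alone. The ages of the models do not overlap either, so this fit cannot decide whether age is the whole difference. Within CTRL and within MODEL2 the older mice had less Rn45s, so trends of age and of Rn45s share cannot be told apart there. An effect of age in one model alone, and a difference between the NFE2L2 changes, in the level of Nfe2l2 or in tumour stage, also remain open and were not tested.

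Other genes and lists differed between the models and are given as log2 fold changes in MODEL2 against MODEL1. The periportal list had a median of 1.53 (camera adjusted p = 0.0413) with Cps1 at 1.97. Its call ended with an estimated correlation (0.243), with fry (0.0575), with the replicate block (0.0565), in the fit of the compared groups alone (0.0558), without CTRL replicate 2 (0.0575), CTRL 3 (0.0548), MODEL1 1 (0.0956) or MODEL2 2 (0.103), and without the libraries rich in Rn45s (0.172). The pericentral genes Glul and Cyp1a2 were at -1.56 and -1.42. Tk1 was at 1.24, Slc27a5 at 1.59, Cyp2a4 at -1.71 and Clec9a at -1.79. The largest rises were Pitx3 at 5.15, H2-M10.6 at 4.07 (both fitted values on 3 counts in MODEL1), Onecut1 at 3.60, Nlrp5-ps at 3.46 and Spryd4 at 3.40. The largest falls were R3hdml at -3.49, Gpr21 at -2.87, Asb13 at -2.77, Pmch at -2.67 and Rnase4 at -2.61.

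Other splits of the libraries were counted for each number of genes. For MODEL1 against CTRL (602 genes), MODEL2 against CTRL (350) and MODEL2 against MODEL1 (192), 1 of 10 splits, the real one, gave as many, and the highest of the others gave 0 by edgeR (158, 154 and 110 genes at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. For the 6 model libraries against the 3 CTRL libraries, a fit of 2 groups called 409 genes. Of 84 splits 1, the real one, gave as many, a share under the bound of 0.05 set for this test. The splits cannot tell an effect of the models from one of age or of what the CTRL mice received. The highest of the others, 180, was the split of the MODEL1 libraries from the rest.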

How the results depend on the processing

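Over 21 alternatives, 72 counts of genes stayed within 1.5 times the reported count, 33 were lower than that and 0 were higher. In the order MODEL1 against CTRL, MODEL2 against CTRL, MODEL2 against MODEL1, mean of both and shared direction, the counts were 299, 71, 101, 151 and 64 with age as a covariate; 399, 199, 69, 369 and 157 at an adjusted p under 0.01; and 233, 87, 22, 156 and 76 with glmTreat. Chosen after seeing the data, they were 261, 137, 72, 236 and 110 among genes with no opposite-strand exon, where 1047 genes were tested, and 274, 207, 70, 296 and 120 without the 3 libraries rich in Rn45s. The stricter thresholds lower a count by construction, and fewer genes were tested in the smaller set; for age and for the libraries rich in Rn45s the cause was not tested. Leaving out each library gave 478 to 596, 221 to 379, 79 to 224, 423 to 550 and 177 to 274. DESeq2 gave 569, 307, 167, 548 and 223. Libraries share only a replicate number: the same-number correlations of deviations were -0.102 to 0.0278, 0 of 9 over 0.1, and the replicate block gave 543, 290, 125, 528 and 220 genes. Lists kept their side of the threshold in 666 comparisons with an alternative, lost it in 22 and gained it in 14, and named genes kept theirs in 1554 and lost it in 188; no direction was reversed among called results. What can be seen is limited, since with 3 libraries per group at these counts 2-fold changes were recovered at 28.7% in simulation. In 9 lists 0 members could be tested, among them the mitochondrially encoded mRNAs, of which 0 of 12 were symbols of the table.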

Other observations

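The tests of the abundant liver mRNAs and of the periportal, cell cycle and cholesterol neighbours were chosen after the result was seen, and the genes named in this part were chosen after their values were seen. Among genes called in MODEL2 in the same direction against both CTRL and MODEL1, 11 were higher and 6 lower. Hectd2, a ubiquitin ligase, was higher in MODEL2 than in CTRL by 1.82 ± 0.18 log2 units and than in MODEL1 by 1.52 ± 0.18 (opposite exon of Hectd2os). Nedd4l, another ubiquitin ligase, was higher by 1.40 ± 0.36 and 2.23 ± 0.38 (opposite exon of A330084C13Rik). The transcriptional repressor Bcl6 had log2 fold changes of -1.45 ± 0.34 and -2.17 ± 0.33 (opposite exon of Gm37419), and the receptor Notch3 of -2.19 ± 0.58 and -2.02 ± 0.58 (opposite exon of Gm17276).

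Abundant liver mRNAs held few counts. Symbols with an opposite-strand exon held 79.0% of the counts of placed symbols, and 91 of the 97 placed symbols among the 100 with the most counts had one. Shallow sampling of whole libraries would keep the order of genes, but Alb ranked 190. Reads from genomic DNA would spread evenly over exons, but among protein-coding genes of 2 to 4 kb those with an opposite-strand exon had 4.94 counts per kb against 0.440 (n = 1462 and 5099), a ratio of 11.2 (bootstrap interval 9.10 to 14.2). Among picked pairs with exon bases shared on opposite strands, Ahsg held 346 counts over all libraries and its neighbour Gm30505 164390. Pzp held 539 and Gm10069 141500, Ppib 20 and Snx22 35847, and Cideb 225 and Nop9 32355. Of the pairs looked at, Gls2 alone went the other way, with 218 against 124 for Spryd4. Alb and Apoa1 had no such neighbour. If the kit marks strand, which the labels do not say, a candidate explanation is that reads were counted on the opposite strand, and no biological explanation was tested.

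If so, a symbol's count could follow its opposite-strand neighbour. For the NRF2, pericentral and periportal lists this could not be tested, since 1 tested symbol lies opposite an NRF2 target (A330041J22Rik, opposite Me1), 1 opposite a pericentral gene (Tomm40l, opposite Nr1i3) and 2 opposite periportal genes (Plbd2, opposite Sds, and Spryd4, opposite Gls2), and a set test needs 3. In MODEL1 against CTRL their log2 fold changes were 0.68 ± 0.30 for A330041J22Rik, -1.62 ± 0.21 for Tomm40l, -3.35 ± 0.38 for Plbd2 and -3.91 ± 0.72 for Spryd4. The cell cycle and cholesterol synthesis lists have 3 such symbols each, but neither list was called in MODEL1 against CTRL, so the lists as sets gave no direction to follow. The called cell cycle members, Tk1 (-2.09 ± 0.22) and Ccna2 (0.88 ± 0.27), each changed in the direction of their neighbour in this comparison. Their changes therefore cannot be told from those of Afmid and Exosc9. Opposite cell cycle genes, Afmid (opposite Tk1) was at -3.57 ± 0.51, Ap4m1 (opposite Mcm7) at 0.08 ± 0.54 and Exosc9 (opposite Ccna2) at 5.61 ± 0.43, with a median of 0.078 and a fry p of 0.628. Opposite cholesterol genes, 4930483K19Rik (opposite Lss) was at -0.52 ± 0.25, Akap9 (opposite Cyp51) at -0.33 ± 0.35 and Ctsb (opposite Fdft1) at 2.11 ± 0.53, with a median of -0.33 and a fry p of 0.927. Over the 3 comparisons of CTRL, MODEL1 and MODEL2 the lowest adjusted fry p of the 6 tests was 0.103. Of the 18 tested symbols opposite a member of any list, 2 were higher and 5 lower in MODEL1 than in CTRL by edgeR's test.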
